A study of Mus musculus with 4 samples.

How the data were processed

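GRO-seq, which labels RNA as polymerases extend it in isolated nuclei and so counts transcription in progress by position and strand, had been run on 3T3-L1 cells, a mouse preadipocyte line. The cells carried a control siRNA (siCTL) or an siRNA against GPS2 (siGPS2), a cofactor of transcription, and had received FCCP, a compound that uncouples mitochondrial respiration, for 0 or 3 hours. The 2 factors give 4 groups with 1 library each.

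The deposited files list aligned reads, 1 line per read, with chromosome, start, end, strand and a score. Bowtie, HOMER and the mouse build mm8 are named in the submitters' processing notes, with no versions. Other steps are not given in the sources used here. The deposited score runs from 0 to 42 and was read as the mapping quality of each read, in which low values mark reads that fit several places in the genome about equally well. No 2 reads of a library share start, end and strand, and the libraries hold equal numbers of reads to within 1, so the files were taken to hold reads after removal of duplicates and thinning to one depth; the original depths are not known. 3 of the libraries each held 1 line with empty leading fields, which were removed.

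The annotation at hand is in another build than the reads, and coordinates were not converted. Genes were therefore not assigned, and the targeted gene, Gps2, and the gene lists drawn up in advance were not analysed here. The unit in their place, set for this case before the data were examined, was the strand-specific window of 10 kb, with each read counted by its 5′ end. Coordinates are mm8 and 1-based. Windows with at least 40 reads over the 4 libraries were tested, 74605 in all, with a median of 33, 32, 27 and 27 reads per window in siCTL, siCTL with FCCP, siGPS2 and siGPS2 with FCCP. Scale factors were medians of ratios to the geometric mean over 35361 windows with at least 20 reads in every library, and came to 1.13, 1.15, 0.875 and 0.880.

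With 1 library per group there is no replicate of any condition. A window was called higher or lower between 2 libraries when the scaled ratio, with 0.5 added to each count, was at least 1.5-fold and an exact Clopper-Pearson interval at a two-sided error of 0.001 excluded no change. The difference of the FCCP responses was called by the same rule on the log2 scale with a Wald interval. Such intervals cover counting error only and compare libraries, not conditions. The named windows are the 5 highest and 5 lowest called per comparison, again a rule set before the data were examined. An additive limma-voom model of siRNA and FCCP over all 4 libraries has 1 residual degree of freedom. It takes its error from the interaction, pooled over windows: the prior degrees of freedom were estimated as infinite, so a window's own residual carries no weight, and its error follows from the trend of variance with count. A window passed at a Benjamini-Hochberg adjusted p under 0.05, two-sided.

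Several steps were added after seeing the data. Reads of mapping quality 10 or more, and of quality 42, were analysed apart. Because siGPS2 reads pile up over short stretches, a second interval was built from the spread of counts between the 50 bins of 200 bp in each window, called the bin interval here. It is a Wald interval, and windows with next to no reads in one library cannot pass it. Runs of consecutive windows called the same way in 2 comparisons were joined into regions; the text names some of the 8 longest in each direction, picked after their values were seen. Ratios of these regions and of the mitochondrial chromosome carry a 95% interval from a jackknife over 200 bp bins. Divergent start sites were found on pooled reads of quality 10 or more, as places where plus-strand reads begin beside minus-strand reads. The pausing ratio compares the first 300 bp with 1 to 5 kb downstream. SEs of medians come from 500 bootstrap draws of whole chromosomes, and those of correlations from a jackknife over chromosomes.

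The calling rule was tested on simulated counting noise over 74605 windows. For FCCP in siCTL it recovered 76% of windows changed 2-fold and 100% of those changed 4-fold, with 46 false calls; in siGPS2 it recovered 64% and 100%, with 40 false calls. For siGPS2 against siCTL it recovered 74% without FCCP and 78% with FCCP at 2-fold, with 43 and 51 false calls. For the difference of the responses it recovered 44% at 2-fold, with 54 false calls. When pile-ups with a mean of 4 reads were simulated in both siGPS2 libraries, the exact interval gave 3887 false calls among 19800 unchanged windows for FCCP in siGPS2, against 86 with the bin interval. For siGPS2 against siCTL the exact interval then gave 1905 without FCCP and 1951 with FCCP, against 70 and 69 with the bin interval. With pile-ups, the bin interval recovered 13 of 100 windows changed 2-fold in siGPS2 and 63 of 100 changed 4-fold. In siCTL it recovered 79 and 100. The additive model recovered 32% at 1.5-fold and 94% at 2-fold, with 10 false calls, under counting noise alone. With a dispersion of 0.02 added it recovered 6% and 34%, with 1 false call. Pile-ups were not simulated for it.

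Alternatives covered the scale factors, the read minimum, the fold and interval of a call, 1 read per 5′ position and strand, 50 kb windows, mapping quality and the limma settings. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1, were used.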

Results

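Nascent transcription was measured in 3T3-L1 preadipocytes with or without knockdown of GPS2, before and after 3 hours of FCCP, to compare the nuclear response to mitochondrial uncoupling between the 2 siRNAs. Each library holds 4200000 reads, or 4200001 in siCTL with FCCP. There are no replicates, so no difference has a replicate check, and every interval covers error within the libraries only. Knockdown could not be checked, since Gps2 was not analysed here.

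The libraries differed in kind as well as by treatment. Reads of mapping quality 1 made up 6.37% of siCTL and 6.63% of siCTL with FCCP, against 30.3% of siGPS2 and 30.0% of siGPS2 with FCCP. Reads of quality 10 or more made up 81.9%, 82.3%, 54.7% and 55.1% in the same order. Among equal numbers of the latter, 2290566 per library, 19.996% and 19.772% of siCTL reads had another read of the same strand within 10 bp, against 47.9% and 45.8% of siGPS2 reads. The variance of counts between 200 bp bins was 1.34 and 1.32 times that of independent reads in the median window of the siCTL libraries, and 5.28 and 4.86 times in the siGPS2 libraries. Exact intervals of siGPS2 against siCTL are therefore too narrow. For FCCP in siGPS2, unevenness that both libraries share leaves their ratio as it is. On chromosome 18, minus strand, 42320001 to 42390000, that ratio's 95% log2 interval was 0.753 to 1.067 from bins and 0.754 to 1.068 from counts. On chromosome 10, minus strand, 82910001 to 82970000, it was 1.23 to 1.73 and 1.30 to 1.67. How far exact intervals are too narrow for FCCP in siGPS2 is not known. Calls by the bin interval stand beside the exact ones. The read names place siCTL without FCCP on sequencing run 183 and the other 3 libraries on 1 lane of run 189. FCCP in siGPS2, and siGPS2 against siCTL with FCCP, are the comparisons within that lane.

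**Figure D1:**
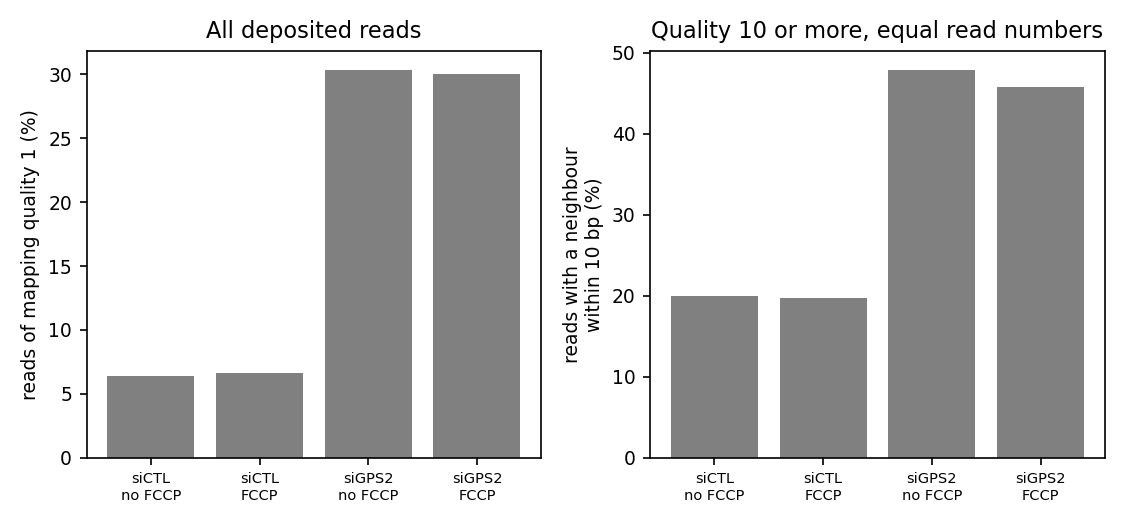
Share of all deposited reads that have mapping quality 1 (left, %) and share of reads of quality 10 or more with another read of the same strand within 10 bp, at equal read numbers (right, %), 1 bar per library. The siGPS2 libraries stand at 30.3% and 30.0% on the left and at 47.9% and 45.8% on the right, above both siCTL libraries.

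Some long stretches of single strands differed between the libraries with FCCP and those without. Wherever a window was called under both siRNAs, the direction was the same. Of such windows, 122 of 477 that rose and 25 of 258 that fell lay in runs of 3 or more. On chromosome 10, minus strand, reads from 82910001 to 82970000 rose 5.85-fold in siCTL (log2 2.55, 95% interval 2.31 to 2.79) and 2.79-fold in siGPS2 (1.48, 1.23 to 1.73). On chromosome 9, minus strand, 61860001 to 61910000 rose 5.30-fold (2.40, 2.07 to 2.74) and 2.67-fold (1.42, 1.18 to 1.65). On chromosome 3, minus strand, 127250001 to 127320000 rose 4.68-fold (2.23, 1.89 to 2.56) and 3.20-fold (1.68, 1.37 to 1.99). The longest region that fell lies on chromosome 15, plus strand, from 27410001 to 27470000, lower by 1.91-fold (-0.93, -1.02 to -0.84) in siCTL and 1.81-fold (-0.86, -0.99 to -0.73) in siGPS2.

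Other regions rose less. Chromosome 8, minus strand, 63790001 to 63850000 rose 2.59-fold and 2.20-fold, and chromosome 18, minus strand, 42320001 to 42390000 rose 2.51-fold and 1.88-fold. Among those that fell, chromosome 3, plus strand, 129540001 to 129570000 was 3.21-fold lower in siCTL and 2.60-fold lower in siGPS2, and chromosome 10, plus strand, 69000001 to 69040000 was 2.67-fold and 2.50-fold lower. In all, windows higher under both siRNAs formed 330 runs, 32 of them of 3 or more windows, and windows lower under both formed 224, 7 of them of 3 or more. The regions were picked on the same reads that give their ratios, so the ratios lean away from 1 and the intervals are not an independent check.

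**Figure D2:**
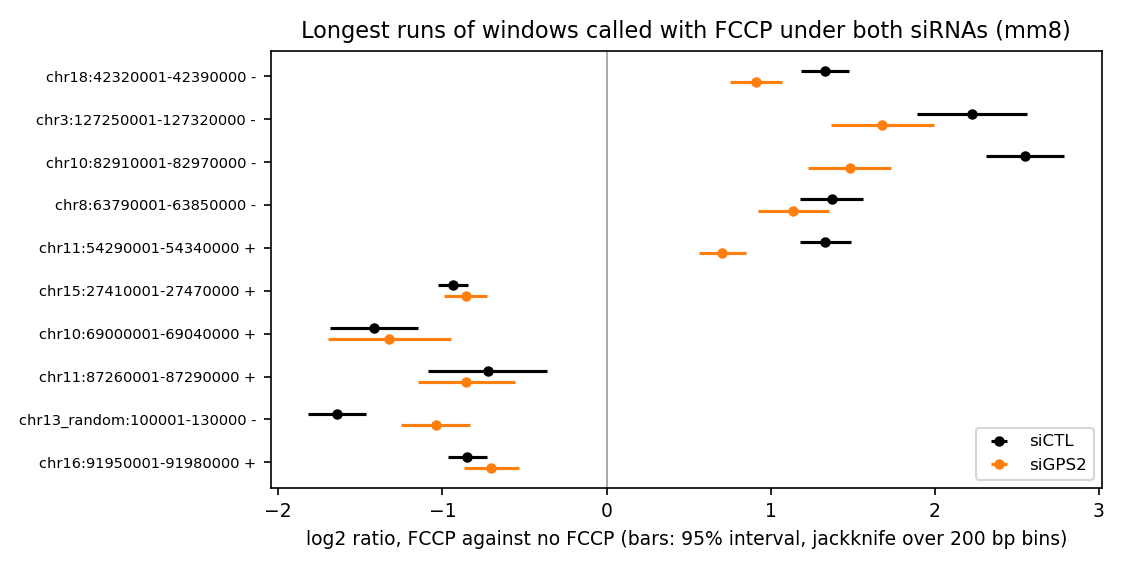
Log2 ratio of reads, FCCP against no FCCP, in the 5 longest regions that rose and the 5 that fell under both siRNAs (mm8 coordinates and strand on the vertical axis). Points are single libraries compared within an siRNA, siCTL in black and siGPS2 in orange, and bars are 95% intervals from a jackknife over 200 bp bins; on chromosome 10, 82910001 to 82970000, siCTL stands at 2.55 and siGPS2 at 1.48.

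In siCTL, FCCP raised 2583 windows and lowered 2664 of 74605 by the exact interval, or 1764 and 1247 by the bin interval. The comparison spans both sequencing runs. Its highest windows had no read before FCCP. Chromosome 10, minus strand, 118370001 to 118380000 went from 0 to 43 reads, at least 14.1-fold higher at a floor of 3 reads per library. Folds given as at least, here and below, set the 0 to this floor. They leave out the counting error of the other count, so they are not lower limits of an interval. Chromosome 3, minus strand, 50480001 to 50490000 went from 0 to 42, at least 13.7-fold, and from 4 to 39 in siGPS2. A pair of adjoining windows on the plus strand of chromosome 3, from 49800001 to 49820000, went from 0 to 25 and from 0 to 26 reads. Its lowest windows held 11 to 15 reads before FCCP and 0 after; chromosome 3, plus strand, 128730001 to 128740000 went from 15 to 0, at least 5.09-fold lower, but 94.6% of its reads over the 4 libraries were below quality 10.

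In siGPS2, within 1 lane, FCCP raised 788 windows and lowered 736 by the exact interval. By the bin interval 40 rose and 4 fell. In simulated siGPS2 reads with pile-ups that interval recovered 13 of 100 windows changed 2-fold and called 86 of 19800 unchanged ones, a larger share than the 44 of 74605 called here. The simulated ratio between the siGPS2 libraries is noisier than the real one, since the exact interval called 3887 of the 19800 there and 1524 of 74605 here. The reason was not tested. The simulation therefore cannot give the number of false calls among the 44, or the share of changed windows that were missed. Their number alone shows no response, and the number of responding windows is not known. Of the 40 that rose, 29 were also called higher in siCTL by the bin interval, where independent lists would share 0.946. The highest window called lies on chromosome 14, minus strand, from 44100001 (log2 5.12), and the lowest on chromosome 2, minus strand, from 105800001 (log2 -4.53). On reads of quality 10 or more the lowest was no longer called. Some of the other named windows follow. Chromosome 2, minus strand, 56970001 to 56980000 went from 1 to 26 reads, 17.6-fold (log2 4.14, exact 95% interval 2.09 to 10.05), and from 3 to 25 in siCTL. Chromosome 15, minus strand, 43580001 to 43590000 went from 2 to 30 reads, 12.1-fold, and from 3 to 19 in siCTL. Chromosome 2, plus strand, 178390001 to 178400000 fell from 20 to 2 reads, and from 31 to 5 in siCTL. Its log2 ratio was -3.19 on reads of quality 10 or more against -3.04 on all reads, but with fewer reads it was no longer called.

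The FCCP responses under the 2 siRNAs, which share no library, overlapped. Both called 477 windows higher, where independent lists would share 27.3, and 258 lower, where they would share 26.3, and 0 were called in opposite directions. Windows with many reads are called more easily in both pairs. Those with 200 or more, 21928 of 74605, held 3112 of the 5247 siCTL calls and 1050 of the 1524 siGPS2 calls. The numbers for independent lists, wherever given, are therefore too low as a baseline. By the bin interval 29 were higher in both, against 0.946, and 1 was lower, against 0.0669. Of windows higher in siCTL 90.7% lay above 0 in siGPS2, and of those lower 87.9% lay below. Across windows, which are not independent replicates, Pearson's r was 0.36 (SE 0.011) and Spearman's rho 0.37; r was 0.27 in windows of 40 to 99 reads and 0.77 in the 1319 windows of 800 or more.

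The additive limma-voom model called 3059 windows higher and 3545 lower with FCCP over both siRNAs. The highest were chromosome 3, minus strand, 50480001 to 50490000 (log2 4.72, SE 0.86, adjusted p = 6.97e-06) and chromosome 3, plus strand, 49800001 to 49810000 (log2 4.57, SE 0.87, adjusted p = 1.87e-05), each higher in 2 of 2 pairs. The lowest was chromosome 2, plus strand, 178400001 to 178410000 (log2 -3.07, SE 0.78, adjusted p = 0.00313), which fell from 47 to 2 reads in siCTL and stood at 3 and 2 in siGPS2. The p-values rest on 4 libraries and on an error that does not model the pile-ups. With total reads or the upper quartile as scale the model called 2340 windows, and with a minimum of 1 read, over 435926 windows, it called 0. Without the library of run 183 it has no residual degree of freedom, and the pair within siGPS2 is what remains.

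Reads from the mitochondrial chromosome fell with FCCP. The siCTL pair spans both sequencing runs. With 1 library per group, a change in mitochondrial transcription cannot be told apart from a difference between libraries. They went from 8109 to 6713 in siCTL (log2 -0.30, 95% interval -0.34 to -0.26) and from 10817 to 7110 in siGPS2 (-0.61, -0.65 to -0.57). On the minus strand the log2 ratio was -0.04 in siCTL, with an interval from -0.14 to 0.07, and -0.38 in siGPS2 (-0.50 to -0.26). Removal of duplicates would compress these ratios, since plus-strand reads started at 35.2%, 27.9%, 49.6% and 32.9% of the chromosome's positions in siCTL, siCTL with FCCP, siGPS2 and siGPS2 with FCCP.

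Knockdown of GPS2 was compared with the control siRNA in each FCCP state. On chromosome 4, plus strand, 136780001 to 136830000 was 4.01-fold lower in siGPS2 without FCCP (log2 -2.00, 95% interval -2.27 to -1.74) and 3.09-fold lower with it (-1.63, -1.88 to -1.38). On chromosome 12, plus strand, 30560001 to 30600000 was 3.67-fold (-1.88, -2.28 to -1.48) and 3.32-fold lower (-1.73, -2.31 to -1.15). On chromosome 15, minus strand, 51630001 to 51690000 was 2.20-fold and 2.15-fold lower. On all reads, the longest region higher in siGPS2 was chromosome 8, minus strand, 126420001 to 126510000, 2.11-fold without FCCP and 1.64-fold with it. Chromosome X, plus strand, 120320001 to 120390000 was 13.9-fold and 15.0-fold higher, from 17 and 15 siCTL reads. With reads of quality 10 or more, which are fewer, the longest run higher in siGPS2 went from 9 windows to 4. Such runs of 3 or more windows went from 107 to 7. For runs lower in siGPS2 the longest went from 6 windows to 5, and those of 3 or more from 54 to 32. The regions above on chromosomes 8, X and 15 therefore did not stay whole. On reads of quality 10 or more, chromosome 7, minus strand, 143020001 to 143060000 was 2.42-fold higher in siGPS2 without FCCP (1.27, 0.99 to 1.55) and 2.18-fold higher with it (1.12, 0.89 to 1.36). On the same reads, chromosome 3, plus strand, 62730001 to 62760000 was 3.11-fold (1.64, 0.76 to 2.51) and 4.04-fold higher (2.01, 1.24 to 2.79). The limit on regions picked and measured on the same reads holds here too.

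By the exact interval 11574 windows were higher and 5693 lower in siGPS2 without FCCP, and 11402 and 4517 with FCCP, within 1 lane. By the bin interval these were 1310 and 2002, and 1434 and 1479. On reads of quality 10 or more and the bin interval, 209 were higher and 1542 lower without FCCP, and 271 and 1001 with it. The split also turned with the scale: 67.0% and 71.6% of calls were higher on the main scale, and 36.8% and 37.1% with total reads, which moved the median log2 ratio of all windows from 0.09 to -0.28 without FCCP and from 0.13 to -0.25 with it. No general direction of the siGPS2 difference is therefore given.

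The highest single windows in siGPS2 rested on low-quality reads. Chromosome 10, minus strand, 6100001 to 6110000 went from 0 to 46 reads without FCCP, at least 19.8-fold, with 94.5% of its reads below quality 10. Chromosome 4, plus strand, 133070001 to 133080000 went from 0 to 45 with FCCP, at least 19.6-fold, with 100% below. The lowest windows rested on reads of higher quality. Chromosome 9, minus strand, 63450001 to 63460000 held 40 reads in siCTL and 0 in siGPS2, at least 10.3-fold lower, and 22 and 6 with FCCP. Chromosome 5, minus strand, 139660001 to 139670000 held 30 reads in siCTL with FCCP and 0 in siGPS2 with FCCP, at least 7.65-fold lower, and 27 and 3 without FCCP.

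The siGPS2 differences in the 2 FCCP states share no library. Both siGPS2 libraries differ in kind from both siCTL libraries, however, and such a difference would recur in both pairs. Their overlap therefore cannot tell the knockdown from a difference in library preparation. By the bin interval 613 windows were higher in both, where independent lists would share 25.2, and 601 lower, against 39.7; 0 went opposite ways. On reads of quality 10 or more these were 73 against 0.979 and 371 against 26.7. Pearson's r across windows was 0.84 (SE 0.0030) with Spearman's rho 0.80, and r was 0.66 on reads of quality 10 or more. The additive model called 21425 windows higher and 13451 lower, or 7529 and 10508 on reads of quality 10 or more. With total reads as scale these were 12931 and 24348, the split the other way, and with a minimum of 1 read 0 were called. Mitochondrial reads were 1.72-fold higher in siGPS2 without FCCP (log2 0.78, 95% interval 0.69 to 0.87) and 1.38-fold with it (0.47, 0.39 to 0.55); with total reads as scale the log2 ratios were 0.42 and 0.08. The plus strand stood at 0.92 (0.81 to 1.03) and 0.65 (0.55 to 0.75), and the minus strand at 0.16 (-0.02 to 0.34) and -0.19 (-0.40 to 0.03). Reads of quality 10 or more placed the minus strand at 0.36 (0.12 to 0.60) and -0.04 (-0.34 to 0.26).

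The FCCP response was compared between the siRNAs in windows selected in either. Windows were selected on one part of the reads and measured on the other, with whole 200 bp bins in each part. The 1293 windows selected as higher in siCTL had a median log2 ratio of 1.06 in siCTL and 0.53 in siGPS2, and the 1154 selected as lower had -0.91 and -0.49, gaps of 0.53 (95% interval 0.47 to 0.59) and 0.42 (0.37 to 0.47), but selection in one siRNA can favour it. Both gaps stayed above 0 on reads of quality 10 or more, 0.45 (0.37 to 0.53) over 1054 windows and 0.41 (0.36 to 0.47) over 986. The 324 selected as higher in siGPS2 had 1.20 in siCTL and 0.78 in siGPS2, a gap of 0.42 (95% interval 0.27 to 0.57). On reads of quality 10 or more that gap was 0.19 (-0.02 to 0.41) over 236 windows, and 0.36 (0.10 to 0.62) over the 47 of them with 400 or more reads. The 334 windows selected as lower in siGPS2 had -0.55 in siCTL and -0.52 in siGPS2, a gap of 0.04 (-0.09 to 0.16). With quality 10 or more it was 0.11 (0.03 to 0.20) over 190 windows, and -0.03 (-0.16 to 0.11) over the 87 with 400 or more reads. Window by window, 138 differences were called higher and 311 lower by the Wald interval from counts, and 4 and 12 by the bin interval.

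In the median, reads close to start sites fell relative to those downstream after FCCP. Over 272 divergent start sites with 367 strands that had enough reads, the pausing ratio changed by a median log2 of -0.40 (SE 0.068) in siCTL and -0.33 (SE 0.068) in siGPS2. The quartiles were -1.08 and 0.18 in siCTL, and -1.08 and 0.22 in siGPS2, so single strands went both ways. The sites were found on the pooled reads that also give the ratios, and the siCTL pair spans both sequencing runs. Dense clusters of reads can pass as sites. Reads of quality 10 or more in chains of 10 or more were 2.39% without FCCP and 1.64% with it in siCTL. In siGPS2 they were 16.1% and 12.8%. A fall near the start that comes from this choice of sites cannot be told apart from a change in pausing. Reads in the first 300 bp went from 4398 to 3400 in siCTL and from 3566 to 2842 in siGPS2. Between the siRNAs the median changes were -0.16 (SE 0.12) without FCCP and -0.10 (SE 0.17) with it, within their error. With all deposited reads they were -0.32 (SE 0.11) and -0.37 (SE 0.12), while the ratio of the summed reads of quality 10 or more changed by 0.20 and 0.36, so no direction is given. At the 63 sites found on siCTL reads alone, they were -1.10 and -0.98, and those for FCCP were -0.71 in siCTL and -0.53 in siGPS2.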

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

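Of the tests weighed here, those of the sequencing run, host transcripts, genomic DNA, dilution and run differences unrelated to the response were chosen, or changed in form, only after the result was seen, as were the bin interval and the use of reads of quality 10 or more. The bound of the dilution test was set beforehand, but after a first run on randomly split reads, which also passed it, the split was changed to whole bins and its error to a bootstrap. The test of run differences first asked for a gap on all reads only, and was changed to ask for it on both sets of reads. The genomic DNA test was first run on windows silent in both siRNAs, where it also passed, and replaced a weaker one on the strands of clusters of reads of quality 1, of which at most 3.33% held both strands in siGPS2.

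For the difference of the FCCP responses, simulated counting noise alone gave 54 false calls among 74605 windows by the Wald interval. Pile-ups were not simulated for it, and the siCTL pair spans both sequencing runs. How many of its calls are false is therefore not known. The FCCP responses were called different between the siRNAs, by the Wald interval from counts on the difference itself, in 449 windows, and by the bin interval in 16. Those with the largest difference above 0 (siGPS2 minus siCTL, log2) lie on chromosome 10, plus strand, from 80990001 (3.71), chromosome 7, plus strand, from 46700001 (3.53), chromosome 9, plus strand, from 106300001 (3.35), chromosome 5, plus strand, from 34950001 (3.29), and chromosome 7, minus strand, from 70190001 (3.23). Those furthest below 0 lie on chromosome 11, minus strand, from 78170001 (-3.91), chromosome 19, minus strand, from 19040001 (-3.62), chromosome 15, minus strand, from 62390001 (-3.53), chromosome 19, plus strand, from 43810001 (-3.42), and chromosome 2, minus strand, from 77750001 (-3.21). On reads of quality 10 or more, those on chromosome 7 and chromosome 15 had fewer reads and were no longer called, at 3.06 from 46700001, 3.43 from 70190001 and -4.06 from 62390001, those on chromosomes 9, 10, 11 and 19 had too few reads to be tested, and those on chromosomes 5 and 2 were called. In the last, reads went from 8 to 131 in siCTL and from 24 to 40 in siGPS2. Mitochondrial reads fell further with FCCP in siGPS2 than in siCTL, with a difference of -0.31 (95% interval from bins, -0.37 to -0.26).

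Both siGPS2 libraries hold more reads of mapping quality 1 than both siCTL libraries. The sequencing run as the whole cause is argued against by a gap of 23.4 percentage points between siGPS2 with FCCP and siCTL with FCCP, which share a lane. Repeats read along with their host transcripts stay open. In windows with no read of quality 10 or more in the libraries of the other FCCP state, the excess per window was 0.568 of that in transcribed windows. Reads of quality 1 fit several places, so one from a transcribed host can be placed in a silent window, and the test cannot decide. Carried-over genomic DNA, which would raise reads of quality 10 or more too, is argued against by windows with no such read in the siCTL library of the other FCCP state, where these rose by at most 0.0228 per window and reads of quality 1 by 2.05 and 2.08. Transcription of repeats after knockdown and a difference in library preparation were not tested and both remain open.

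The siGPS2 reads of quality 10 or more pile up over short stretches. A candidate explanation is that they come from diverged copies of the repeats that hold the reads of quality 1. Of piled reads 14.32% without FCCP and 13.002% with it had such a read within 100 bp, against 6.04% and 5.59% of lone reads. In siCTL the shares were 12.2% and 10.9% of piled reads against 1.06% and 1.10% of lone reads, so this nearness is not particular to siGPS2. The siGPS2 share is above that of lone reads but below the 50% set beforehand, so this explanation cannot be told apart from others, such as uneven amplification, which was not tested.

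On all reads, windows that rose with FCCP rose less in siGPS2. Dilution by repeat reads or an even background should spare windows with many reads. In windows that rose, a gap of 0.36 (0.10 to 0.62) remained in 47 windows with 400 or more reads of quality 10 or more. That argues against dilution as the whole cause there. A part stays open, since over all 236 windows of such reads the gap was 0.19 (-0.02 to 0.41), down from 0.42 on all reads. In windows that fell, dilution stays open. The gap on such reads was 0.11 (0.03 to 0.20) over 190 windows and -0.03 (-0.16 to 0.11) in the 87 with 400 or more. Fewer usable reads in siGPS2 are argued against by siCTL reads thinned to the siGPS2 number, which still gave 2.71 times the calls (2978 against 1099), although thinning does not copy the pile-ups. Run differences unrelated to the response stay open, since the answer turned with the reads: the gap lay beyond its error on all reads but not on those of quality 10 or more in windows that rose (0.42, and 0.191 as above), and the other way round in windows that fell (0.0383, -0.09 to 0.16, and 0.11, 0.03 to 0.20). Run differences of any kind and an effect of the knockdown cannot be told apart, since siCTL without FCCP is the only library of its run, so a weaker response after knockdown stays untested.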

How the results depend on the processing

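Mapping quality, the bin interval, bins as parts of the reads, robust fits, total reads as scale and 1 read per position for mitochondrial reads, sites found in siCTL and all deposited reads for the pausing ratio were chosen after seeing the data; the other settings were set beforehand. With total reads as scale the median siGPS2 ratio of all windows changed sign and the share of calls that were higher turned, as the report gives. Of 86 counts of called windows 45 stayed within 1.5 times and 41 did not; of 347 values of named windows 333 stayed called and 14 did not, but many settings leave a window's counts as they are, and of 50 named windows 29 could be tested at quality 10 or more (23 called), 18 at quality 42 (15 called) and 1 with 200 reads; of 92 other values 66 stayed within their error and 26 did not. The planned settings for gene bodies, whole genes, the start of the gene, gene lists and Gps2 were not run, since genes were not assigned. The cause was not tested unless given here. Depth limits the single windows, whose median is 27 to 33 reads per library. Counts are given in the order FCCP in siCTL, FCCP in siGPS2, siGPS2 without FCCP, siGPS2 with FCCP and difference of the responses, leaving out those that stayed within 1.5 times.

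With a minimum of 1 read, siGPS2 without and with FCCP gave 30006 and 29810 windows, r of the FCCP responses was 0.0531 and r of the siGPS2 differences 0.55. Limma, with prior degrees of freedom of 1.26, or 1.11 in the robust fit, then called 0 windows for FCCP and 0 for siGPS2, with and without robust empirical Bayes, although 36146 and 161217 had an unadjusted p under 0.05 (33300 and 151305 with the robust fit). With 200 reads fewer windows were tested: FCCP in siCTL gave 3112 and siGPS2 5947 and 5432, the r were 0.60 and 0.83, and limma called 4158 for FCCP and 10563 for siGPS2. There the siCTL median of windows lower in siCTL was -0.86, and that of windows higher in siGPS2 was 1.09.

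With a 2-fold minimum, FCCP gave 3321 and 781 and the difference 288. With a 95% interval the 5 counts were 13916, 7454, 31726, 30262 and 5728. With 50 kb windows FCCP in siCTL gave 3294, r of the FCCP responses was 0.30 and limma called 3902 for FCCP. With total reads, and with the upper quartile, limma called 2340 for FCCP; in both, 282 windows had no residual, the prior degrees of freedom fell from infinite to 11.6, and the robust fit gave 4952. Mitochondrial log2 ratios of siGPS2 were 0.42 and 0.0829 with total reads.

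On reads of quality 10 or more, siGPS2 gave 7474 and 6021 windows, the r were 0.42 and 0.66, limma called 18037 for siGPS2, and the mitochondrial ratios of siGPS2 were 0.96 and 0.62. Windows higher in siCTL had a median of 0.61 in siGPS2. Windows higher in siGPS2 had 1.31 in siCTL and 1.04 in siGPS2, and those lower -0.78 and -0.63. On quality 42, FCCP in siGPS2 gave 726, siGPS2 5408 and 3911 and the difference 229, the r were 0.39 and 0.61, and limma called 13239 for siGPS2.

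With the bin interval the 5 counts were 3011, 44, 3312, 2913 and 16, and on reads of quality 10 or more 2693, 59, 1751, 1272 and 17; a wider interval calls fewer windows by construction. With bins as parts, windows lower in siGPS2 had a siGPS2 median of -0.52, and on reads of quality 10 or more those higher in siCTL had 0.61 in siGPS2. At sites found in siCTL the pausing ratio changed by -0.71, -0.53, -1.10 and -0.98; choosing sites on siCTL reads favours reads near the start in siCTL.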
